A study of Mus musculus with 9 samples.

How the data were processed

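The samples were CD4+ T cells sorted by flow cytometry from tumours of mice given an anti-AXL antibody intraperitoneally and collected on day 16. The labels do not say from which event the days were counted. They name 3 groups of 3 samples each, namely PD-1-negative Foxp3-negative cells, PD-1-positive Foxp3-negative cells and regulatory T cells (Treg). A table of T cell receptor beta chain (TRB) clonotypes was used for replicate 1 of each group, so 3 of the 9 samples were analysed and the other 6 samples were not analysed here. All 9 samples carry the same treatment label, so no comparison of antibody with untreated tumours was made. Per the labels' protocols, total RNA libraries were made with a SMARTer mRNA kit. Tumours were digested with collagenase and DNase, and sorted cells were frozen in lysis buffer. The mouse strain, the tumour line, the number of sorted cells per tube and whether the same-numbered libraries share a mouse are not given in the labels.

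Each deposited table lists clonotypes, defined by the authors, with a read count, a fraction of reads, the best V, D, J and C gene hits with alignment scores, the nucleotide and amino-acid sequence of the CDR3 (the complementarity-determining region 3, which spans the V-D-J junction) and the lowest base quality in the CDR3. The deposited read count is a whole number of reads per clonotype, with no normalization and no molecular identifiers, per the file headers. The deposited fraction is that count divided by the total of the listed reads. The deposited quality score of the CDR3 ran from 21 to 58 over the 3 tables and was not used as a filter. The program, its version, its germline library and its filters are not given in the sources used here. Clone numbers run past the number of listed rows. Of these, 263, 471 and 600 numbers are absent for the PD-1-negative, PD-1-positive and Treg libraries, so each list is part of a longer one and its total is that of the listed TRB reads, not of the whole RNA library. No table holds a clonotype with a stop codon or a frame shift, so the planned filter on productive sequences removed 0 clonotypes.

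For the calculations described here, a clonotype was a CDR3 nucleotide sequence with its best V and J gene. Read depth differed between libraries (452707, 297248 and 676813 reads), so clonality and clonotype number were computed after drawing 297248 reads from each library without replacement, in 200 seeded draws. The PD-1-positive library is the smallest and was used whole, so its values have no spread. Clonality was 1 minus the Shannon entropy divided by the logarithm of the clonotype number, and lies between 0 for equal clonotypes and 1 for a single dominant one. Shares carry 95% exact Clopper-Pearson intervals. Means of CDR3 properties carry 95% bootstrap intervals over clonotypes from 1000 seeded draws. The difference between the means of a pair of libraries was called where its bootstrap interval excluded 0, and the difference in usage of a single gene where the exact intervals did not overlap. For usage weighted by reads, bootstrap intervals over clonotypes took the place of the exact intervals. A call lost under that weighting therefore does not mean a gap within read-counting error. Summed shares of a gene list were compared by the bootstrap interval of the difference. Reads amplified by PCR are not independent molecules, so all intervals other than the bootstrap intervals over clonotypes, and the limits of 3 counts given for a count of 0, cover counting error only. The bootstrap intervals cover the drawing of clonotypes within a library. No interval covers differences between animals. With 1 library per group, no test between groups was possible and no p-value is given. The values compare these libraries and not the sorted populations in general.

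Overlap was the number of identical clonotypes in a pair of libraries, its share of the shorter list, and the Morisita-Horn index of the read shares, which is 0 for no overlap and 1 for the same shares. Its range came from 200 draws of the reads with replacement. Hydrophobicity was the mean Kyte-Doolittle value of CDR3 residues 6 and 7, counted from 1 at the first CDR3 residue. Inserted nucleotides were those between the trimmed V, D and J ends, from the positions in the tables. Shared and private clonotypes were compared within a library by the percentile of the shared set's median among 10000 random sets of the same size. The named V and J genes were chosen by a rule fixed before the data were examined. It takes each gene whose intervals did not overlap between 2 libraries, the 5 most used V genes of each library, and the members of 5 fixed lists used by at least 1% of clonotypes in a library. The lists were the TRBV13 family, the V genes used by invariant natural killer T (NKT) cells, 6 of the V genes of cells that mouse mammary tumour virus superantigens delete in some strains, and the TRBJ1 and TRBJ2 clusters. Named clonotypes were the 5 largest of each library, up to 5 per pair and up to 10 in all 3 libraries with the highest geometric mean of share. The limit of 1000 reads for a large clonotype was chosen after the read counts were seen.

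Gene positions are from GENCODE release M21 on the mouse assembly GRCm38, matched by gene name for 36 of the 36 V and J segments named in the tables. The tables hold no genomic coordinates. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9. The usage comparison was tested on 50 simulated pairs per comparison with 4 V genes changed. A change of 3 times was recovered in 100% of cases in each of the 3 pairs. A change of 1.5 times was recovered in 69.5% of cases at the sizes of the PD-1-positive and PD-1-negative lists, 75% at those of the Treg and PD-1-negative lists and 85% at those of the Treg and PD-1-positive lists. With no change, an average of 0.16, 0.06 and 0.08 V genes were called in these pairs. Each simulated clonotype drew its V gene independently. Near copies, within 2 nucleotides of a clonotype with the same V and J gene and at least 20 times the reads, break this independence. They made up 13.0%, 25.9% and 21.0% of the PD-1-negative, PD-1-positive and Treg lists. The simulated rate of false calls does not cover them and may be too low for these lists. Alternatives were the clonotype definition, minimum counts of 2 and 10, full depth, weighting by counts, removal of shared clonotypes and of near copies of larger clonotypes, and other measures of hydrophobicity. A difference is said to turn or reverse where its sign changed, whether or not the new difference was called.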

Results

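The T cell receptor beta chain repertoire was read from RNA of 3 CD4+ T cell subsets sorted from tumours of mice that had received an antibody against AXL, a receptor tyrosine kinase, and were sampled on day 16. PD-1 is an inhibitory receptor carried by activated and chronically stimulated T cells, and Foxp3 is the transcription factor that defines regulatory T cells (Treg). The PD-1-negative Foxp3-negative library held 452707 reads in 1088 clonotypes, the PD-1-positive Foxp3-negative library 297248 reads in 1716 clonotypes, and the Treg library 676813 reads in 1998 clonotypes. Each group is represented here by 1 library, so there are no replicates and every comparison below is between single libraries. The series title places the work in resistance to immune checkpoint blockade. The clonotype lists address how the receptor repertoires of the 3 subsets differ and overlap within antibody-treated tumours.

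The PD-1-negative library was dominated by the fewest clonotypes. Its 10 largest clonotypes took 81.2% of reads (95% exact interval 81.1% to 81.3%), against 40.4% (40.2% to 40.6%) in the PD-1-positive and 32.3% (32.2% to 32.4%) in the Treg library. The most abundant 6 clonotypes made up 50% of the PD-1-negative reads, where 18 and 22 were needed in the PD-1-positive and Treg libraries. Clonality at equal depth was 0.564 (range over draws 0.563 to 0.565) in PD-1-negative, 0.424 in PD-1-positive and 0.402 (0.401 to 0.404) in Treg cells. At 297248 reads the number of clonotypes was 964 (947 to 982), 1716 and 1475 (1442 to 1511) in the same order. Equal read depth does not equalise the number of sorted cells, which is not given. A smaller number of cells in the PD-1-negative library therefore cannot be told apart from a higher clonality of the cells. The order of the PD-1-positive and Treg libraries depended on depth and on rare clonotypes. At full depth clonality was 0.426 in Treg against 0.424 in PD-1-positive cells, with 1998 against 1716 clonotypes. With clonotypes of at least 2 reads, clonality was higher by 0.00607 and the clonotype number by 208 in Treg than in PD-1-positive cells, and with at least 10 reads the PD-1-positive number fell by 47 below that of the PD-1-negative library. Without clonotypes within 2 nucleotides of one with at least 20 times the reads, the PD-1-positive number was 435 above the PD-1-negative one and the Treg number 1186 against 1272 in PD-1-positive cells.

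Most reads sat in a small set of large clonotypes. Clonotypes of at least 1000 reads numbered 18, 71 and 77 in the PD-1-negative, PD-1-positive and Treg libraries and held 94.5%, 91.5% and 94.4% of their reads. The median large clonotype had 21273 reads in PD-1-negative, 2654 in PD-1-positive and 7718 in Treg cells. Clonotypes with a single read made up 28.8%, 45.0% and 36.8% of the lists but only 0.0691%, 0.260% and 0.109% of the reads.

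**Figure D1:**
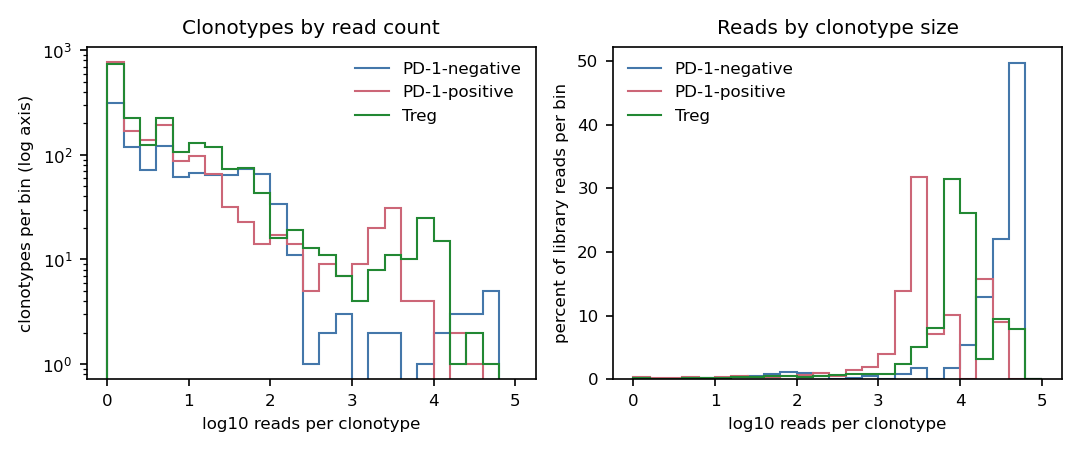
Number of clonotypes (left, log axis) and percent of library reads (right) by log10 reads per clonotype, in bins of 0.2, for the 3 libraries. The reads of each library concentrate in the upper part of the axis, and the 18 PD-1-negative clonotypes of at least 1000 reads hold 94.5% of that library.

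The largest PD-1-negative clonotype, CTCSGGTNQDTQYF with TRBV1 and TRBJ2-5 (CDR3 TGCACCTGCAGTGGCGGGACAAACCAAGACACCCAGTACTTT), took 12.3% of reads (12.3% to 12.4%). It was followed by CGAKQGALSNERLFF (TRBV20, 9.95%), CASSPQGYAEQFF (TRBV19, 9.42%), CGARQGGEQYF (TRBV20, 9.10%) and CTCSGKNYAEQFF (TRBV1, 8.97%). The PD-1-positive library was led by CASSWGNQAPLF (TRBV15 and TRBJ1-5, 8.91%), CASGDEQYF (TRBV13-2 and TRBJ2-7, 8.36%) and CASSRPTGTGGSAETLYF (TRBV19 and TRBJ2-3, 7.36%), ahead of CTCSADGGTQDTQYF (TRBV1, 2.75%) and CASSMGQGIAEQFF (TRBV19, 2.51%). The Treg library was led by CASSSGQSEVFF (TRBV19 and TRBJ1-1, 7.95%), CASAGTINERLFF (TRBV16 and TRBJ1-4, 4.90%), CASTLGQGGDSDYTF (TRBV19, 4.49%), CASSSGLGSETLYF (TRBV15, 3.22%) and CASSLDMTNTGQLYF (TRBV16, 2.22%). None of the 5 leading clonotypes of the PD-1-negative library exceeded 21 reads in another library. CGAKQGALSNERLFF was not found in the PD-1-positive library, where a count of 0 allows a share of up to 0.00101%.

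PD-1-positive Foxp3-negative cells and Treg shared clonotypes of high read count, and PD-1-negative cells shared no clonotype that was large in both libraries of a pair. The PD-1-positive and Treg libraries had 233 identical clonotypes, 13.6% (12% to 15.3%) of the shorter list, and these held 64.4% of the PD-1-positive and 52.9% of the Treg reads. Their Morisita-Horn index was 0.0842 (range 0.0830 to 0.0853). In this pair 9 clonotypes had at least 1000 reads in both libraries, 12.7% (6.0% to 22.7%) of the 71 large PD-1-positive clonotypes, and accounted for 19.0% of the PD-1-positive and 12.9% of the Treg reads. The PD-1-negative library had 65 clonotypes in common with the PD-1-positive and 43 with the Treg library, 5.97% (4.64% to 7.55%) and 3.95% (2.87% to 5.29%) of its list, with indices of 0.000207 (0.000152 to 0.000272) and 0.000190 (0.000167 to 0.000216). The clonotypes shared with PD-1-positive cells held 58.9% of PD-1-negative and 19.8% of PD-1-positive reads, and those shared with Treg 32.8% of PD-1-negative and 35.3% of Treg reads. Of its 18 large clonotypes 0 were large in either other library, which allows a share of up to 16.7%. Requiring at least 10 reads in both libraries left 63 shared clonotypes in the PD-1-positive and Treg pair, 6 with PD-1-positive and 5 with Treg cells in the PD-1-negative pairs. The 63 held 49.6% of PD-1-positive and 30.9% of Treg reads, the 6 held 9.02% of PD-1-negative and 0.855% of PD-1-positive reads, and the 5 held 0.0873% of PD-1-negative and 2.63% of Treg reads. This limit still keeps large clonotypes with few reads in the other library. Among the 63, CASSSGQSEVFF held 7.95% of Treg reads with 29 PD-1-positive reads, and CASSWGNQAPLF 8.91% of PD-1-positive reads with 42 Treg reads. Among the 6, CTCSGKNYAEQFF held 8.97% of PD-1-negative reads with 21 PD-1-positive reads. The shares of the 9 clonotypes large in both libraries, given above, do not include these. Near copies of larger clonotypes were not removed from the shared counts, which may be inflated by them. Among the 63 were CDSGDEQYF (355 PD-1-positive and 50 Treg reads) and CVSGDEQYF (242 and 69). Each differs by 1 residue from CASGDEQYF (24851 and 4817 reads), with the same V and J gene.

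The shared clonotype with the highest geometric mean of share was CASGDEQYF (TRBV13-2 and TRBJ2-7, CDR3 TGTGCCAGCGGTGATGAACAGTACTTC), with 24851 reads in PD-1-positive cells and 4817 in Treg, or 8.36% (8.26% to 8.46%) and 0.712% (0.692% to 0.732%) of reads. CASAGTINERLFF (TRBV16) had the opposite weighting, 0.771% in PD-1-positive cells and 4.90% in Treg. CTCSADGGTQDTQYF (TRBV1) took 2.75% and 1.11%, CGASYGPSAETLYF (TRBV20) 1.99% and 1.42%, and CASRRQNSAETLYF (TRBV15) 1.26% and 1.33% of PD-1-positive and Treg reads. The remaining large shared receptors were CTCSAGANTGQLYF (TRBV1), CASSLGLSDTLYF (TRBV16), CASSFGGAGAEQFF (TRBV3) and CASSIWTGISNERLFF (TRBV19), named after their values were seen. In the pairs with PD-1-negative cells, the Treg clonotype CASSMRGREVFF (TRBV19, 8123 reads) had 227 PD-1-negative reads, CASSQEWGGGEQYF (TRBV5, 9476 Treg reads) had 39, and the PD-1-positive clonotype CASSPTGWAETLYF (TRBV5, 2423 reads) had 46. In the other direction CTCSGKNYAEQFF (TRBV1) had 40607 PD-1-negative and 21 PD-1-positive reads, and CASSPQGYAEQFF (TRBV19) had 42655 PD-1-negative, 1 PD-1-positive and 2 Treg reads. The 3 libraries had 22 clonotypes in common, 17 of them with at least 1000 reads in a library and 0 with at least 100 reads in each.

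**Figure D2:**
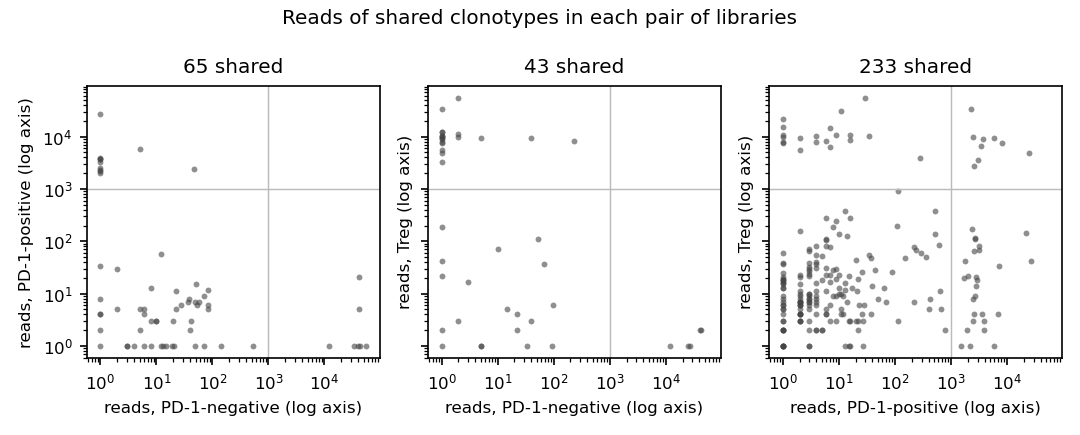
Reads of each shared clonotype in both libraries of a pair, on log axes, with grey lines at 1000 reads. The pair of PD-1-positive and Treg libraries has 9 of 233 points in the upper right field, and the pairs with the PD-1-negative library have 0 of 65 and 0 of 43.

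Within a library, shared clonotypes ranked higher than private ones in 5 of the 6 comparisons, and in 3 of these also with clonotypes of at least 2 reads. Clonotypes with more reads can be detected or carried over more readily, so the ranks alone do not show sharing between the cell populations. Clonotypes of equal count were ordered by their sequence. In the PD-1-positive library the clonotypes shared with Treg had a median rank of 434 by reads, against 935 for the others, below all 10000 random sets of the same size (percentile 0). In the Treg library the medians were 500 and 1089 (percentile 0). The PD-1-negative clonotypes also found in Treg were the exception, with a median rank of 717 against 543 (percentile 98.5), and this became percentile 11 with clonotypes of at least 2 reads. In the Treg library the same 43 clonotypes had a median rank of 176 against 1009 (percentile 0). Of these, 16 had at least 1000 Treg reads and 1 or 2 PD-1-negative reads, and so ranked low in the PD-1-negative list. The median rank of PD-1-positive clonotypes shared with PD-1-negative cells was 537 against 870 (percentile 0.060), but lay at percentile 51.7 with at least 2 reads. For PD-1-negative clonotypes shared with PD-1-positive cells it was 363 against 558 (percentile 0.160, and 2.85 with at least 2 reads). Median CDR3 length was 14 residues for shared and private clonotypes except in the PD-1-negative and Treg pair, where the shared median was 13 (percentile 0.760 in the PD-1-negative and 5.18 in the Treg library, but 14.1 and 34 with at least 2 reads). In the PD-1-positive and PD-1-negative pair the mean length of shared clonotypes was lower, 13.5 against 13.9 in both libraries. Its percentile was 1.93 in the PD-1-negative and 4.94 in the PD-1-positive library. For clonotypes shared by PD-1-positive cells and Treg the mean length lay at percentiles 27.6 and 57.9. The median number of inserted nucleotides was 3 for shared and for private clonotypes in all 6 comparisons, at percentiles of 48.8 to 56.2. The mean, examined after the medians were seen to be tied, was lower for shared clonotypes in each comparison. It was 2.85 against 3.59 (percentile 0) in the PD-1-positive and 2.85 against 3.40 (percentile 0.235) in the Treg library for the clonotypes shared by both. For those shared by PD-1-positive and PD-1-negative cells the percentiles were 1.77 and 3.63, and for the PD-1-negative and Treg pair 23.3 and 30.6.

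TRBV19 (chromosome 6, 41178375 to 41179048, GRCm38) was the most used V gene in all 3 libraries, with 14.1% (12.1% to 16.3%) of PD-1-negative, 20.8% (18.9% to 22.8%) of PD-1-positive and 17.8% (16.2% to 19.6%) of Treg clonotypes. Between PD-1-positive and PD-1-negative cells the intervals of 8 V genes did not overlap. TRBV19, TRBV15 (6.70% against 3.95%), TRBV12-2 (1.57% against 0.368%) and TRBV14 were higher in PD-1-positive cells, and TRBV20 (5.36% against 10.7%), TRBV1 (6.93% against 10.6%), TRBV5 (5.71% against 8.73%) and TRBV12-1 (0.291% against 1.56%) were lower. TRBV14 (chromosome 6, 41135145 to 41135616) was seen in 17 PD-1-positive clonotypes and in 0 of 1088 PD-1-negative clonotypes, which allows a share of up to 0.276%. Near copies of large clonotypes bear on these counts: without clonotypes within 2 nucleotides of another with the same V and J gene and at least 20 times the reads, only TRBV20 (5.50% against 10.8%) of the 8 genes still differed. The shorter lists widen the intervals, and the other gaps also narrowed. As a part of the former gap, the narrowing was less for TRBV1 (6.92% against 9.61%), TRBV5 (5.90% against 8.13%), TRBV12-1 (0.314% against 1.27%) and TRBV14 (0.786% against 0%). It was more for TRBV19 (17.1% against 13.6%), TRBV15 (5.19% against 3.91%) and TRBV12-2 (1.10% against 0.422%). With V scores of at least 200 the TRBV20 difference was not seen (4.17% against 4.5%) and the TRBV19 call ended (18.02% against 15.6%), and TRBV5 turned to 2.48% against 1.40% of reads when weighted by reads. Weighted by reads, with bootstrap intervals over clonotypes, TRBV1 (9.16% against 26.7%), TRBV20 (4.04% against 19.5%), TRBV15, TRBV19 and TRBV12-1 lost the call at wider gaps. TRBV14 lost it at a smaller gap. With at least 10 reads TRBV19 (24.2% against 17.1%), TRBV15, TRBV14 and TRBV12-2 lost the call at wider gaps. TRBV20 and TRBV12-1 lost it at smaller ones.

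Between Treg and PD-1-positive cells 9 V genes differed. Treg used more TRBV5 (9.71%, 8.45% to 11.1%, against 5.71%, 4.66% to 6.92%), TRBV1 (10.4% against 6.93%), TRBV16 (10.7% against 7.98%), TRBV13-3 (4.70% against 2.68%) and TRBV12-2 (3.65% against 1.57%). They used less TRBV13-2 (chromosome 6, 41121396 to 41121832; 7.31%, 6.20% to 8.54%, against 13.5%, 11.9% to 15.2%), TRBV15 (4.35% against 6.70%), TRBV26 (0.601% against 1.63%) and TRBV14 (0.0501% against 0.991%). Between Treg and PD-1-negative cells 3 V genes differed: TRBV12-2 (chromosome 6, 41118851 to 41119364) was higher in Treg, at 3.65% (2.87% to 4.57%) against 0.368% (0.10% to 0.939%), and TRBV13-2 (7.31% against 11.1%) and TRBV20 (chromosome 6, 41188273 to 41188977; 5.01% against 10.7%) were lower. Both of the lower genes turned under another setting, TRBV20 to 5.36% against 4.5% with V scores of at least 200 and TRBV13-2 to 6.36% against 4.71% with at least 10 reads. TRBV31, among the 5 most used V genes of PD-1-positive cells, was at 7.72%, 7.17% and 6.16% in PD-1-negative, PD-1-positive and Treg cells, with overlapping intervals. Without the near copies of larger clonotypes, TRBV1, TRBV5, TRBV12-2, TRBV13-2 and TRBV14 still differed between Treg and PD-1-positive cells, and TRBV12-2 and TRBV20 between Treg and PD-1-negative cells. With at least 10 reads the TRBV12-2 calls ended (2.23% in Treg against 1.69% in PD-1-positive and 0.248% in PD-1-negative cells), the former also weighted by reads (3.31% against 2.25%), and the TRBV14 call ended with at least 2 reads (0.0792% against 0.847%). Weighted by reads, TRBV1 turned to 7.64% in Treg against 9.16% in PD-1-positive cells. The TRBV5 call of that pair ended with V scores of at least 200 (5.36% against 4.32%), and that of TRBV26 with at least 2 reads (0.475% against 0.530%).

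**Figure D3:**
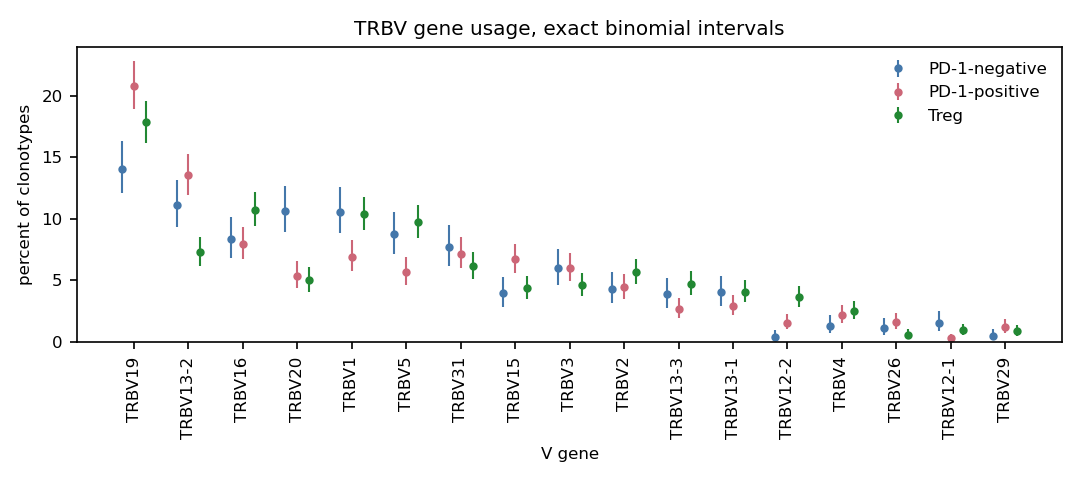
Percent of clonotypes using each TRBV gene that reached 1% in a library, with 95% exact binomial intervals as bars, for the 3 libraries. TRBV19 is the most used gene in each library, and TRBV13-2 is at 7.31% in Treg against 13.5% in PD-1-positive cells.

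Of the fixed V gene lists, 6 V genes of T cells that viral superantigens delete in some mouse strains (TRBV12-1, TRBV12-2, TRBV15, TRBV16, TRBV17 and TRBV26) together made up 16.3% (14.1% to 18.6%) of PD-1-negative, 19.2% (17.3% to 21.1%) of PD-1-positive and 20.9% (19.1% to 22.7%) of Treg clonotypes. The share was higher in Treg than in PD-1-negative cells by 4.60 percentage points (bootstrap interval 1.61 to 7.47) and in PD-1-positive than in PD-1-negative cells by 2.9 points (0.0548 to 5.74). Treg minus PD-1-positive was 1.70 points (-0.834 to 4.30), and gained a call with at least 10 reads (6.11, 0.706 to 11.5), with V scores of at least 200 (2.94) and without near copies (2.97). The PD-1-positive call ended without near copies of larger clonotypes (1.98 points), with V scores of at least 200 (0.661, -2.42 to 4.17) and weighted by reads (12.02, -10.5 to 29.4), and turned with at least 10 reads (-1.18), and the Treg call ended weighted by reads (18.04, -3.86 to 34.9) and with at least 10 reads (4.93, -0.397 to 10.1). The members went both ways. Between Treg and PD-1-negative cells only TRBV12-2 of the 6 differed, TRBV12-1 was lower and TRBV12-2 and TRBV15 were higher in PD-1-positive than in PD-1-negative cells, and TRBV15 and TRBV26 were lower and TRBV12-2 and TRBV16 higher in Treg than in PD-1-positive cells. Superantigens also delete cells with V genes outside the list, TRBV19, TRBV29 and TRBV13-3 among them, so the sum is that of these 6 genes only. The TRBV13 family held 19.0%, 19.1% and 16.1% of PD-1-negative, PD-1-positive and Treg clonotypes. PD-1-positive cells were above PD-1-negative ones only with at least 10 reads (7.56 points, 2.58 to 11.99) and weighted by reads (15.3, 3.02 to 31.8), and the Treg share was lower than the PD-1-positive share (difference in points -3.05, -5.47 to -0.563), a call that ended weighted by reads (-12.1, -28.8 to 0.913). The Treg share was also lower than the PD-1-negative share (-2.96, -5.78 to -0.279), but this call ended with at least 2 reads (-1.39), with V scores of at least 200 (-2.50) and without near copies (-1.19). The difference turned with at least 10 reads (2.46, -1.68 to 6.42) and weighted by reads (3.15, -1.56 to 8.18), both without a call. Within the family TRBV13-2 was lower in Treg, TRBV13-3 was higher in Treg than in PD-1-positive cells, and TRBV13-1 was at 4.04%, 2.91% and 4.05% with overlapping intervals. The V genes that invariant NKT cells use, a cell type that a CD4 gate can hold, made up 30.1%, 27.3% and 27.3% of clonotypes. No difference was called between the libraries, except that PD-1-positive cells were below PD-1-negative ones without clonotypes found in several libraries (-3.88 points, -7.54 to -0.259). These genes are also used by conventional T cells, and TRBV29 among them took 0.460%, 1.22% and 0.851%.

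Fewer J genes than V genes were called as differing, among 12 J genes and 23 or 24 V genes per pair. Near copies of larger clonotypes were not removed for J genes. TRBJ2-7 was the most used J gene throughout, with 18.5% (16.2% to 20.9%), 17.3% (15.5% to 19.2%) and 16.3% (14.7% to 18%) of PD-1-negative, PD-1-positive and Treg clonotypes. TRBJ2-3 was higher (13.5% against 9.83%) and TRBJ2-2 lower (6.06% against 10.2%) in PD-1-positive than in PD-1-negative cells, and TRBJ1-1 was higher in Treg than in PD-1-positive cells (12.7%, 11.3% to 14.3%, against 8.1%, 6.85% to 9.49%). No J gene differed between Treg and PD-1-negative cells. The TRBJ1 cluster held 32.3% (29.5% to 35.1%), 32.4% (30.2% to 34.7%) and 35.1% (33.0% to 37.2%) of clonotypes and TRBJ2 the rest, with no difference between libraries beyond the bootstrap interval. The other TRBJ1 genes ranged from 2.51% for TRBJ1-6 to 7.40% for TRBJ1-4, both in PD-1-positive cells, and TRBJ2-1, TRBJ2-4 and TRBJ2-5 from 7.08% to 12.2%. With clonotypes of at least 2 reads the intervals of TRBJ2-2 (5.83% against 9.16%) and TRBJ2-3 (13.1% against 10.7%) overlapped, and with at least 10 reads those of TRBJ1-1 did as well, although its shares (15.5% in Treg against 10.7% in PD-1-positive cells) stayed as far apart on the shorter lists. Weighted by reads, with bootstrap intervals over clonotypes, TRBJ2-3 (19.7% of PD-1-positive against 4.04% of PD-1-negative reads) and TRBJ2-2 (3.27% against 13.4%) lost their calls at wider gaps. So did TRBJ1-1 between Treg and PD-1-positive cells (20.6% against 6.05%).

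The CDR3s of the 3 subsets had about the same length and central hydrophobicity when each clonotype was counted once. Mean CDR3 length was 13.9 residues (13.8 to 14) in PD-1-negative, 13.9 (13.8 to 13.9) in PD-1-positive and 13.8 (13.7 to 13.9) in Treg clonotypes, and the Treg minus PD-1-negative difference was -0.116 residues (-0.243 to 0.00721). Mean Kyte-Doolittle hydrophobicity at residues 6 and 7 was -1.13 (-1.23 to -1.05), -1.12 (-1.20 to -1.05) and -1.23 (-1.31 to -1.16). The Treg value differed by -0.0954 (-0.216 to 0.0180) from PD-1-negative and by -0.110 (-0.213 to 0.00162) from PD-1-positive clonotypes, so no difference was detectable at this number of clonotypes. With at least 2 reads per clonotype, PD-1-positive and Treg CDR3s were less hydrophobic than PD-1-negative ones, by -0.178 (-0.321 to -0.0274) and -0.200 (-0.352 to -0.0612). Convergent receptors, amino-acid CDR3s encoded by more than 1 nucleotide clonotype, made up 7.12% (5.60% to 8.90%), 6.14% (5.01% to 7.43%) and 6.63% (5.53% to 7.86%) of distinct sequences and did not differ between libraries. With at least 10 reads, convergent receptors were 8.83% of PD-1-positive and 3.17% of PD-1-negative sequences.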

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

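The tests of carry-over within each pair and of the evenness of large clonotypes were chosen only after the result was seen. So was the count of clonotypes within 2 nucleotides of larger ones.

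The C gene column, which entered no comparison of the subsets, named TRBC2 as the best hit for nearly all clonotypes with a TRBJ1 gene, although TRBC1 lies between the TRBJ1 and TRBJ2 clusters on chromosome 6 (41538218 to 41539881, GRCm38). TRBC2 was named for 99.4% (98.0% to 99.9%) of TRBJ1 clonotypes in the PD-1-negative, 99.6% (98.7% to 100%) in the PD-1-positive and 99.1% (98.1% to 99.7%) in the Treg library. The same gene was named for 99.7%, 99.6% and 99.6% of TRBJ2 clonotypes, and both C genes were listed as hits for 340 of 351, 549 of 556 and 677 of 701 TRBJ1 clonotypes. Both were also listed for 728 of 737, 1143 of 1160 and 1264 of 1295 TRBJ2 clonotypes with a C hit. The best hit was thus nearly the same for both clusters and does not show which C gene a TRBJ1 clonotype used.

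The sharing of clonotypes between libraries was weighed against carry-over of reads between libraries and against independent recombination of easily made sequences. For sharing as a whole, the ratios of recipient to donor reads among the 20 largest clonotypes spread over 13902 times from PD-1-positive cells to Treg and 5409 times the other way, but only 2.30 to 28.9 times in the 4 directions with the PD-1-negative library, and 5 to 13 of the 20 were found, which argues against a fixed carry-over rate as the cause of all sharing (at ratios near 3e-05 only very large donors would be seen, so the number found decides little). Between PD-1-positive cells and Treg, 9 of the 56 shared clonotypes with at least 1000 reads in at least 1 of the libraries had a smaller share over 10% of the larger, more than a low rate of carry-over leaves (not all of these are among the 9 with at least 1000 reads in both). In the pairs with the PD-1-negative library the picture stayed open. Clonotypes with at least 1000 reads in a library had a median of 1 read in its partner, as carry-over would give. However, 55.4% of the clonotypes shared with PD-1-positive cells and 25.6% of those shared with Treg had a smaller share over 10% of the larger. All of these were under 1000 reads in both libraries. Independent recombination could not be told apart from sharing of descent, since ties at a median of 3 inserted nucleotides held the percentiles near the middle (highest 56.2) whatever the means; the mean, examined afterwards, was low for the clonotypes shared by PD-1-positive cells and Treg (percentiles 0 and 0.235) and less so for those shared by PD-1-positive and PD-1-negative cells (1.77 and 3.63) and by PD-1-negative cells and Treg (23.3 and 30.6), and cells sorted through the wrong gate or a common origin of Treg and Foxp3-negative clones remain open.

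The 2 levels of read counts, many clonotypes at a few reads and a set of at least 1000 reads, were weighed against sequencing errors and against the number of sorted cells. At most 0.130% of single-read clonotypes lay 1 nucleotide from another with at least 20 times the reads, a value that would speak against errors, but 12.1%, 37.3% and 26.1% lay within 2 nucleotides of such a clonotype in the PD-1-negative, PD-1-positive and Treg libraries, against 3.51%, 1.30% and 0.951% for clonotypes seen only in another library, the higher of the other two. That control left out clonotypes found in both libraries, which held 64.4% of PD-1-positive and 52.9% of Treg reads in their pair. Its targets were not matched in number or size, so the control shares may be too low. Clonotypes at 1 nucleotide from one with at least 20 times the reads were listed, 72, 120 and 169 of all sizes, but hardly any with a single read, so that distance decides nothing about single reads, and errors may account for part of the rare clonotypes. The large clonotypes lay within 2 times of their median count in at least 55.6% of cases in each library, which is consistent with each standing for 1 or a few cells, but the limit of 1000 reads narrows that spread and the number of sorted cells is not given, so this cannot be told apart from expansion of clones in the tumour.

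TRBV19 was more frequent among large than among smaller Treg clonotypes, at 31.2% (21.1% to 42.7%) against 17.3% (15.6% to 19.0%), while in PD-1-positive cells 31.0% (20.5% to 43.1%) and 20.4% (18.4% to 22.4%) overlapped. Wrong V gene calls on short alignments are a candidate explanation, since 20.4% to 23.4% of clonotypes in the 3 libraries had a V score under 200 and 8.58% of the CDR3s found in a pair of libraries carried different V calls. With V scores of at least 200 the TRBV19 shares were 28.0% (16.2% to 42.5%) of large and 17.6% (15.6% to 19.8%) of smaller PD-1-positive clonotypes, and 23.5% (12.8% to 37.5%) and 13% (11.3% to 14.8%) in Treg. The higher point estimates stayed, but the intervals overlapped with only 50 and 51 large clonotypes, so a part played by V calls cannot be told apart from usage of TRBV19 by the cells behind large clonotypes.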

How the results depend on the processing

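Alternatives added after the data were examined are the limits of 100 and 1000 reads, the 1% carry-over limit, the V score of 200, the fixed CDR3 ends, the 2-nucleotide removal and the read limits of 500 and 2000. No paired analysis was possible because clonotypes of 1 library per group were used here, which also leaves no replicate to leave out. Of 446 recomputed values, 288 counted as unmoved, 96 lost and 12 gained a call, 29 moved and 21 reversed; a difference whose interval included 0 before and after counts as unmoved, and numbers of differing genes were compared as numbers only. Weighted by counts, PD-1-positive and PD-1-negative cells had 2 differing J genes but 0 of the former, whose gaps widened. Treg and PD-1-negative cells then had 4 V genes with 1 of the former 3. For PD-1-positive and PD-1-negative cells, 1 of the former 8 V genes was kept weighted by counts, 4 with at least 2 and 2 with at least 10 reads. Differences in top-10 share kept direction and call in all 15 alternatives (Treg minus PD-1-positive -9.20 to -8.11 points). Keeping non-productive sequences (0 listed) changed nothing. Unless stated, the cause was not tested.

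Clonality, Treg minus PD-1-positive, turned to 0.00607 with at least 2 reads, 0.0379 with at least 10 and 0.00239 at full depth, and clonotype number to 208, 226 and 282. The PD-1-positive minus PD-1-negative number was 187 with at least 2 reads and -47 with at least 10, the Treg minus PD-1-positive number -86.1 without near copies, and the Treg minus PD-1-negative number 179 with at least 10 reads. Shared clonotypes of PD-1-positive with PD-1-negative cells fell to 31, 6 and 0 with at least 2, 10 and 100 reads, those of Treg with PD-1-negative cells to 18, 5 and 1 (18 under the 1% carry-over limit), and those of Treg with PD-1-positive cells to 63 and 18 with at least 10 and 100. With at least 10 reads the Morisita-Horn indices of the PD-1-negative pairs were 0.000139 and 0.000151.

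The number of differing V genes, PD-1-positive and PD-1-negative, was 5 weighted by counts, 5 with at least 2 reads, 3 with at least 10, 5 with a V score of at least 200, 0 with at least 1000 reads and 1 without near copies. For Treg and PD-1-negative cells it was 5 with the V score and 0 with at least 1000 reads; for Treg and PD-1-positive cells 2 weighted by counts, 3 with at least 10 reads, 0 with at least 1000 and 5 without near copies. The 18, 71 and 77 clonotypes of at least 1000 reads are too few for this count to speak of lost differences, since even TRBV13-2 at 2.60% in Treg against 11.3% in PD-1-positive cells had overlapping intervals. Differing J genes were 2 for Treg and PD-1-negative and 0 for Treg and PD-1-positive cells weighted by counts, 0 for PD-1-positive and PD-1-negative cells with at least 2 and with at least 10 reads, and 2 and 0 for Treg and PD-1-positive cells. Single V gene differences that turned, in percentage points, were TRBV5 for PD-1-positive minus PD-1-negative (1.08), TRBV13-2 for Treg minus PD-1-negative (0.864) and TRBV1 for Treg minus PD-1-positive (-1.51) weighted by counts, TRBV13-2 for Treg minus PD-1-negative (1.64) with at least 10 reads, and TRBV20 for Treg minus PD-1-negative (0.853) with the V score. The TRBV13 family for Treg minus PD-1-negative turned to 3.15 weighted by counts and 2.46 with at least 10 reads, and the superantigen list for PD-1-positive minus PD-1-negative to -1.18 with at least 10 and -1.10 with at least 1000 reads.

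Without clonotypes found in several libraries, the Treg minus PD-1-negative TRBJ1 share was 3.84 points and CDR3 length -0.150 residues, and the Treg minus PD-1-positive hydrophobicity was -0.129; all then excluded 0. Without near copies the PD-1-positive minus PD-1-negative length was -0.165 and the Treg minus PD-1-negative hydrophobicity -0.149. Hydrophobicity, PD-1-positive minus PD-1-negative, was -0.178 with at least 2 and -0.277 with at least 10 reads, and Treg minus PD-1-negative -0.200 with at least 2. Convergent clonotypes, PD-1-positive minus PD-1-negative, were 5.67 points with at least 10 reads and near copies left in. With at least 2 reads the median rank of PD-1-negative clonotypes shared with PD-1-positive and with Treg cells lay at percentiles 2.85 and 11, their CDR3 length with Treg at 14.1, and the rank of PD-1-positive clonotypes shared with PD-1-negative cells at 51.7. Depth limits the rare clonotypes, since 28.8% to 45.0% of each list rests on a single read, and at the smallest library total the shared clonotypes of the 3 pairs numbered 59.5 and 30.2 with PD-1-negative cells (PD-1-positive, Treg) and 215.6 without them.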

Other observations

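The comparison of large with smaller clonotypes was chosen after the read counts were seen. Large clonotypes had shorter CDR3s than the rest in 2 of the 3 libraries. In Treg the mean length was 13.3 residues (12.9 to 13.6) for the 77 clonotypes of at least 1000 reads and 13.8 (13.7 to 13.9) for the others, a difference of -0.514 (-0.855 to -0.157). In the PD-1-negative library it was 13.1 (12.3 to 13.7) for 18 large clonotypes and 13.9 (13.8 to 14) for the rest (-0.855, -1.59 to -0.178), and in the PD-1-positive library the difference was -0.0421 (-0.450 to 0.357). The large Treg clonotypes also had fewer inserted nucleotides, 2.74 (2.27 to 3.18) against 3.36 (3.22 to 3.52), while the corresponding differences in the PD-1-negative (-0.885, -2.07 to 0.742) and PD-1-positive (0.0146, -0.649 to 0.664) libraries had intervals that included 0.

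Weighted by reads, TRBV19 took 37.0% of the Treg, 31.2% of the PD-1-positive and 21.7% of the PD-1-negative library, TRBV16 19.4%, 6.08% and 1.45%, and TRBV1 7.64%, 9.16% and 26.7%. TRBV13-2 took 15.5% of PD-1-positive reads, of which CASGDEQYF alone made 8.36%, against 1.49% in Treg and 0.629% in PD-1-negative cells. The TRBJ1 cluster carried 48.5% of Treg, 30.6% of PD-1-positive and 22.7% of PD-1-negative reads.

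A hypothesis set before it was tested was that T cells with like receptors had expanded, which would bring pairs of large clonotypes with nearly identical CDR3s but different nucleotide sequences. Among the 139 different clonotypes of at least 1000 reads in the PD-1-positive and Treg libraries there were 5 pairs with CDR3s of the same length at 0 or 1 amino-acid differences. Random sets of as many smaller clonotypes gave 3.79 such pairs on average (95% range 1 to 9), which put the observed number at percentile 74.8, so the data did not decide for or against it. Near copies of larger clonotypes, 444 of 1716 in the PD-1-positive and 419 of 1998 in the Treg list, were left in and can form such pairs. The observed pairs were not checked for copies of a larger clonotype either, so the percentile does not measure expansion alone. The pairs were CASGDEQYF (TRBV13-2) in 2 nucleotide forms with 24851 and 3119 PD-1-positive reads, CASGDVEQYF and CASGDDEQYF (TRBV13-2) in PD-1-positive cells, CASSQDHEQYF (TRBV5) in 2 nucleotide forms with 3830 and 1911 Treg reads, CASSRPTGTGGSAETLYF and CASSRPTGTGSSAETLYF (TRBV19) with 21887 and 2878 PD-1-positive reads, and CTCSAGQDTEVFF and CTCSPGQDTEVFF (TRBV1) with 3148 and 2050 PD-1-positive reads.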
